A study of Mus musculus with 6 samples.

How the data were processed

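Messenger RNA was sequenced from mouse ovarian granulosa cells of 2 genotypes, Il22r+/+ and Il22r-/-, with 3 libraries each, and each library was placed in its group by the genotype in the labels and by its title. The labels' protocols state isolation by density gradient, 12 h in serum-supplemented culture and a standard Illumina library preparation. Read length, strand setting, aligner and read filters are not given in the sources used here.

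The authors deposited a table of raw read counts for 55860 genes with Ensembl identifiers. Per the submitters' processing notes, featureCounts 1.5.0-p3 and the mm10 build were used. The counts were whole numbers, summed to 17.7 M, 17.43 M and 17.52 M (M, mega-reads) in Il22r+/+ replicates 1 to 3 and to 18.11 M, 18.12 M and 14.95 M in Il22r-/- replicates 1 to 3, and were tested as deposited. The authors also deposited FPKM values, that is, counts scaled by gene length and by a library total. Count divided by length and FPKM gave 1 constant per library over genes with more than 50 counts, so the deposited FPKM came from the same counts. That constant lay between 0.936 and 1.05 times the library's count total, so each total had been rescaled by a factor of its own, by a method not given in the sources used here. FPKM values were used only as an alternative.

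Genes with enough counts in either group (filterByExpr of edgeR, 15227 genes) were normalised with TMM factors and tested in edgeR 4.0.16 with the robust quasi-likelihood fit (glmQLFit and glmQLFTest), genotype being the only term. Log2 fold changes are Il22r-/- minus Il22r+/+. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. CPM values are counts per mega-read (M) of the library after TMM normalisation. The group values are means ± SD over 3 libraries, and the errors of log2 fold changes are standard errors of the fit. Counting intervals are exact at 95%, the floor of a count of 0 is 3 counts, and both cover counting error only. P-values reflect the spread between these 6 libraries alone, since the labels do not say whether they came from separate animals or cultures, and that spread may be technical.

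Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with the estimated correlation beside it and with fry. Adjustment ran over the 15 pathway lists and, separately, over the 14 lists of quality and cell type markers, and lists with fewer than 3 tested members got no test. Calls near Il22ra1, taken as the targeted gene, were counted within 10 Mb and compared with the remaining tested genes by a two-sided Fisher's exact test. Principal components were taken from log2 CPM (prior count 2) of the 500 most variable genes.

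The groups, tests, gene lists, alternatives and naming rule were fixed before the data were examined. The rule named the receptor genes, the 12 largest changes in each direction among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups (symbols that are only clone or model numbers passed over), up to 4 called members of each list by size of change (or the most abundant 2 where none was called), and a few genes of STAT3 signalling, steroid synthesis and ovulation. Genes named outside it are said to have been chosen after their values were seen, and a few genes that the rule names are not reported here. Gene positions, GC content, exon lengths and exon overlaps came from the GENCODE M21 annotation of the mm10 assembly.

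Alternatives were DESeq2 1.42.0 (its Wald test, and its size factors in edgeR), limma-voom, scaling by library size alone, no filter and a stricter filter on low counts, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, each library left out in turn, and other window sizes. A correction for GC content and transcript length, and a fit without mitochondrially encoded genes, were added after seeing the data. R was 4.3.3.

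The edgeR step was tested on simulated counts for the same 15227 genes, 3 against 3, with 200 genes changed. Every simulated gene had the same dispersion (spread between replicates beyond sampling noise), 0.01386. The edgeR step recovered 55.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold. It called 18 of 15027 unchanged genes, 10% of its calls, which is above the share that the adjusted p threshold aims for. In the deposited counts far more genes were called, and the spread between replicates differed between the groups. The simulated rates therefore cannot be carried over to the deposited counts. Replicates of a group differed by more than sampling noise: the chi-square statistic per gene lay between 4.76 and 6.77 for pairs of Il22r+/+ libraries and between 10.2 and 27.3 for pairs of Il22r-/- libraries, so none was counted as a duplicate.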

Results

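Granulosa cells are the somatic cells that surround the oocyte in the ovarian follicle and make steroid hormones. Transcripts were counted in cultured granulosa cells of Il22r+/+ mice and of mice lacking the receptor for interleukin-22, a cytokine whose receptor signals through JAK kinases and STAT3. Each genotype had 3 libraries, with counted reads of 17.43 M to 17.7 M in Il22r+/+ and 14.95 M to 18.12 M in Il22r-/-. The series title concerns interleukin-22, STAT3 and ovulation in polycystic ovary syndrome, and the comparison asks which transcripts differ when the receptor gene is disrupted. Every library carried the female transcript Xist, at 673 to 921 CPM, and no read of the Y-linked genes Kdm5d and Ddx3y.

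The receptor gene taken here as the targeted one was hardly expressed in either genotype. Il22ra1 (ENSMUSG00000037157, mm10 chromosome 4, 135728172 to 135752140, plus strand), which encodes the ligand-binding receptor chain, had 1, 5 and 4 reads in Il22r+/+ replicates 1 to 3 and 5, 2 and 0 in Il22r-/- replicates 1 to 3. Pooled, this was 10 of 52.65 M reads (0.19 CPM, exact 95% interval 0.0911 to 0.349) against 7 of 51.18 M reads (0.137 CPM, 0.055 to 0.282), with an exact binomial p of 0.63. Il22ra2, the soluble decoy receptor, and Il22 itself had no reads in any library, which allows at most 0.057 CPM in pooled Il22r+/+ and 0.0586 CPM in pooled Il22r-/-. The shared chain Il10rb (ENSMUSG00000022969) had 30.2 ± 1.01 CPM (SD, n = 3) in Il22r+/+ and 36.6 ± 7.33 CPM in Il22r-/-, a log2 difference of 0.28 ± 0.13 that did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.113). Il10rb passed edgeR without Il22r-/- replicate 3 (adjusted p = 0.00354), with library size alone (0.0454) and with no filter (0.0398), in a range up to 0.469 over the alternatives. Gm21970 shares 14.9% of its exon length on the same strand. The labels do not name the receptor's full symbol or the deleted exon, and at these counts Il22ra1 could not check the genotype labels.

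The genotypes differed across a large part of the transcriptome. Among the genes ranked by the naming rule, all with a mean of at least 5 CPM, the largest fall was that of Smpd3 (ENSMUSG00000031906, chromosome 8, 106252548 to 106337988). Smpd3, a neutral sphingomyelinase, had 279.9 ± 23.9 CPM in Il22r+/+ and 1.39 ± 0.575 CPM in Il22r-/- (199.7-fold lower, log2 change -7.64 ± 0.19). Bnc1, a zinc-finger transcription factor, fell 64.9-fold, the membrane glycoprotein gene Gpm6a 48.5-fold, Camkv 60.8-fold and Tmem108, with 15.6% of its exon length overlapped by Gm16252, 35.9-fold. The surface proteins Upk1b and Msln fell 34.5-fold and 29.0-fold, and Col6a2, Slit3, Dcn, Clmn and Fam163a fell between 22.7-fold and 25.8-fold. In the other direction, Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose 40.9-fold from 0.415 ± 0.159 to 17.3 ± 4.81 CPM. Col1a2, a chain of type I collagen, rose 37.9-fold from 1.61 ± 1.18 to 61.3 ± 32.9 CPM, and Actg2, a smooth muscle actin, rose 31.4-fold. Zfp385b, Col6a3, Myh11, Cxcl14, Stc1, C1s2, Fgd5, Ccl17 and the desmosome gene Dsp rose between 14.3-fold and 21.8-fold. The naming rule required that in these 24 genes the 3 libraries of one genotype lay wholly above the 3 of the other. Their edgeR quasi-likelihood adjusted p-values ran from 8.09e-09 for Smpd3 and Gpm6a to 0.00222 for Cxcl14. Of the 24, Upk1b, Msln, Dcn, Col1a2 and Myh11 are also on the marker lists of other cell types below. Bnc1 and Gpm6a are on a mesothelial list picked after their values were seen. Leaving out 1 library moved several folds by over 1.5 times without ending the call: Col1a2 had a log2 change of 5.95 without Il22r+/+ replicate 1, Myh11 5.04 without that library, Cxcl14 3.34 and Camkv -6.83 without Il22r-/- replicate 2, and Bnc1 -6.67 without Il22r-/- replicate 1.

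**Figure D1:**
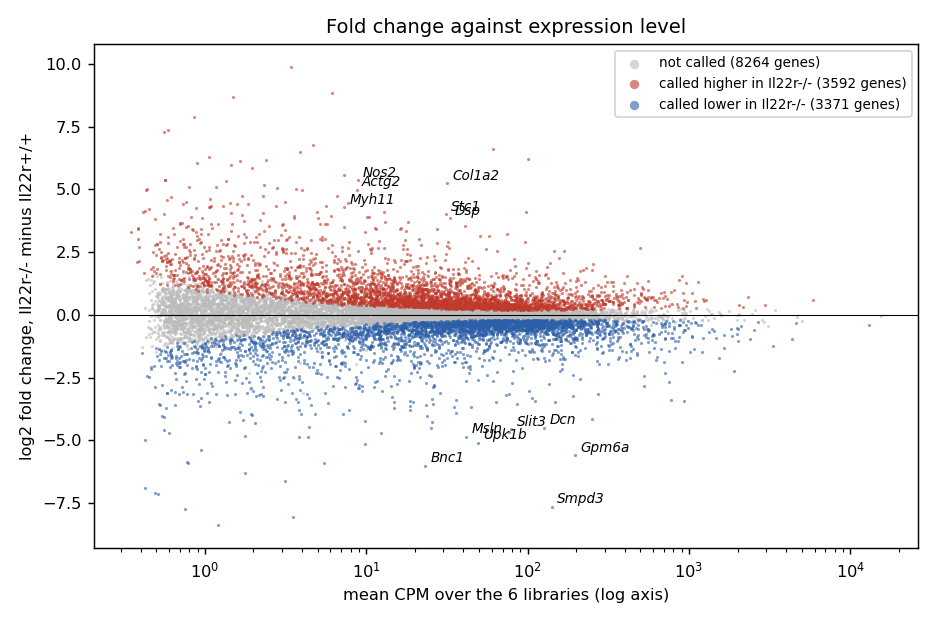
Each point is 1 of the 15227 tested genes, with its mean CPM over the 6 libraries on a log axis and its log2 fold change, Il22r-/- minus Il22r+/+, on the vertical axis. Red marks the 3592 genes called higher in Il22r-/-, blue the 3371 called lower and grey the genes not called by the edgeR quasi-likelihood test. The labelled genes are among the largest changes under the naming rule, with Nos2 and Col1a2 above and Smpd3 at -7.64 below.

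By the edgeR quasi-likelihood test, 6963 of 15227 tested genes (45.73%) were called, 3592 higher and 3371 lower in Il22r-/-, and 2181 of them changed at least 2-fold (1222 higher, 959 lower). The counts of called list members below are to be read beside this share and its near-even split by direction. Among all tested genes, 55.97% had no overlap between the 3 libraries of each genotype, where chance gives 10%. With library size as the only scaling, 63.6% of calls were higher instead of 51.59%, and the median gene lay 0.103 higher on the log2 scale, so small changes are relative to the TMM scale. The first principal component held 89.35% of the variance of the 500 most variable genes and separated the genotypes. Il22r-/- replicate 3 stood apart from the other libraries on the second (score 14.5, against -8.93 to 1.22, 4.21% of variance), and without it 8243 genes were called, 2480 of them at least 2-fold.

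Transcripts of Stat3 and of most tested STAT3 target genes were lower in Il22r-/-. STAT3 protein and its activity were not measured here. Il22 had no reads in any library and Il22ra1 only 10 in Il22r+/+, so the counts do not show whether interleukin-22 signalling was lost. Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540) fell from 251 ± 12.5 to 134 ± 5.95 CPM, a log2 change of -0.91 ± 0.08 with an edgeR quasi-likelihood adjusted p of 7.55e-06. Socs3, the feedback inhibitor that STAT3 induces, fell from 30.6 ± 4.33 to 12.1 ± 0.983 CPM (log2 change -1.34 ± 0.13). Of 24 listed STAT3 targets 17 were tested, of which 12 fell and 2 rose, with the same counts adjusted over the list alone. Saa1, Saa2, Saa3, Lcn2, Reg3b, Reg3g and Lrg1 had too few reads for a test. Lif, a cytokine of the interleukin-6 family, fell from 40.9 ± 1.05 to 7.74 ± 1.59 CPM, and the haemoglobin-binding acute phase gene Hp from 3.72 ± 0.356 to 0.216 ± 0.154 CPM (log2 change -4.01, and -4.63 without Il22r-/- replicate 2). Steap4, a metalloreductase, fell from 8.41 ± 1.45 to 0.356 ± 0.616 CPM, with 20 Il22r-/- reads, all in replicate 2. Its log2 change of -4.47 was -10.17 without that library and -3.86 without Il22r-/- replicate 1, and the DESeq2 Wald test ended the call (adjusted p = 0.0614, in a range from 4.41e-06 over the alternatives). The size of -10.17 is set by the fit, since no Il22r-/- read was left. Against the list's direction, Fgl2, a fibrinogen-like immune regulator, had 2 reads in Il22r+/+ and 154 in Il22r-/- (ratio 79.2, exact 95% interval 21.6 to 660), and its fitted log2 change of 5.95 was 8.65 without Il22r+/+ replicate 2. Both Il22r+/+ reads were in that library, so the size of 8.65 is set by the fit. The growth regulator Myc, a member named after its values were seen, rose from 86.0 ± 5.39 to 212.7 ± 23.1 CPM. The list was lower by camera (adjusted p = 0.00139, median log2 change -0.45; adjusted p = 0.154 with an estimated correlation).

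Among the receptor's own signalling parts, 3 of 7 tested genes changed, a share near the 45.73% called among all tested genes. Stat3 fell, as given above, and the kinase gene Tyk2 rose from 27.0 ± 2.54 to 35.4 ± 2.22 CPM. Tyk2 lost its call in limma on unfiltered FPKM values (adjusted p = 0.0539, in a range from 0.000533 over the alternatives). Counts adjusted over the list alone were also 1 higher and 2 lower, and camera gave an adjusted p of 0.942, with a median of 0.17 above 0 and a mean of -0.17 and a test direction below it.

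Genes of steroid hormone synthesis moved in both directions. Star, which carries cholesterol into the mitochondrion, fell from 224 ± 28.0 to 98.4 ± 17.2 CPM (log2 change -1.19 ± 0.14). Cyp11a1, the side-chain cleavage enzyme that makes pregnenolone, rose from 646 ± 73.9 to 1618 ± 186 CPM (1.33 ± 0.12), and Hsd3b1, which makes progesterone from it, rose from 561 ± 87.9 to 1354 ± 314 CPM (1.27 ± 0.18). Nr5a2, a nuclear receptor needed for ovulation, rose from 52.3 ± 3.66 to 174 ± 26.9 CPM, and Srd5a1 rose 2.31-fold. Cyp19a1, the aromatase, had 8, 3 and 25 reads in Il22r+/+ and 0, 0 and 1 in Il22r-/-, below the test's filter (ratio 35, exact interval 5.89 to 1420, Il22r+/+ over Il22r-/-). For the list of 14 tested genes 6 rose and 4 fell, 6 and 5 adjusted over the list alone, and camera called no shift (adjusted p = 0.942), the median being -0.16 and the mean and test direction above 0. Exons of Srd5a1 are shared over 16.4% with Gm17108.

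Granulosa identity and follicle growth genes were likewise split, 5 higher and 5 lower of 16 tested, and 6 and 6 adjusted over the list alone. Fshr, the follicle-stimulating hormone receptor, rose from 0.257 ± 0.183 to 5.99 ± 1.10 CPM, and Amhr2, the receptor of anti-Müllerian hormone, from 37.1 ± 3.97 to 103 ± 5.98 CPM. Serpine2, a protease inhibitor of growing follicles, fell from 2364 ± 74.8 to 725 ± 122 CPM. Lhcgr, the luteinizing hormone receptor, was below the filter with 0, 0 and 3 reads in Il22r+/+ and 23, 13 and 3 in Il22r-/- (pooled ratio 13.4, exact interval 4.25 to 67.6), so replicate 3 of both genotypes had the same number of reads and the ratio depends on single libraries. Camera gave the list an adjusted p of 0.942, with a median of -0.14 against a mean of 0.26 and a test direction above 0.

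Ovulation and cumulus expansion genes included large changes of both signs. Vcan, a hyaluronan-binding proteoglycan, rose 10.8-fold from 4.63 ± 0.506 CPM, and Pgr, the progesterone receptor, from 7 to 81 reads (log2 change 3.40 ± 0.48, and 3.996 without Il22r+/+ replicate 3). Ptgs2, the inducible cyclooxygenase, fell 1.65-fold from 148 ± 8.62 CPM (edgeR quasi-likelihood adjusted p = 0.0133). The EGF-like ligand Ereg and the cytokine Il6 also fell (log2 changes -1.55 ± 0.25 and -2.85 ± 0.45). Has2, which makes hyaluronan, had 1.42 ± 0.421 and 2.61 ± 1.63 CPM and did not pass (edgeR adjusted p = 0.218), although it passed without Il22r-/- replicate 1 (edgeR adjusted p = 0.00712) and with no filter (0.0427), in a range up to 0.538 over the alternatives. Of 20 tested members 6 rose and 8 fell, 6 and 9 adjusted over the list alone, and camera called no shift (adjusted p = 0.566). In the luteinization list 3 of 11 rose and 4 fell (3 and 5 adjusted over the list alone), with the receptors Ptgfr and Prlr 5.72-fold and 2.73-fold higher and the cell cycle inhibitor Cdkn1a falling 3.21-fold from 565 ± 13.9 CPM. The luteinization list's camera adjusted p was 0.523, while fry called the list lower (adjusted p = 0.0147).

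**Figure D2:**
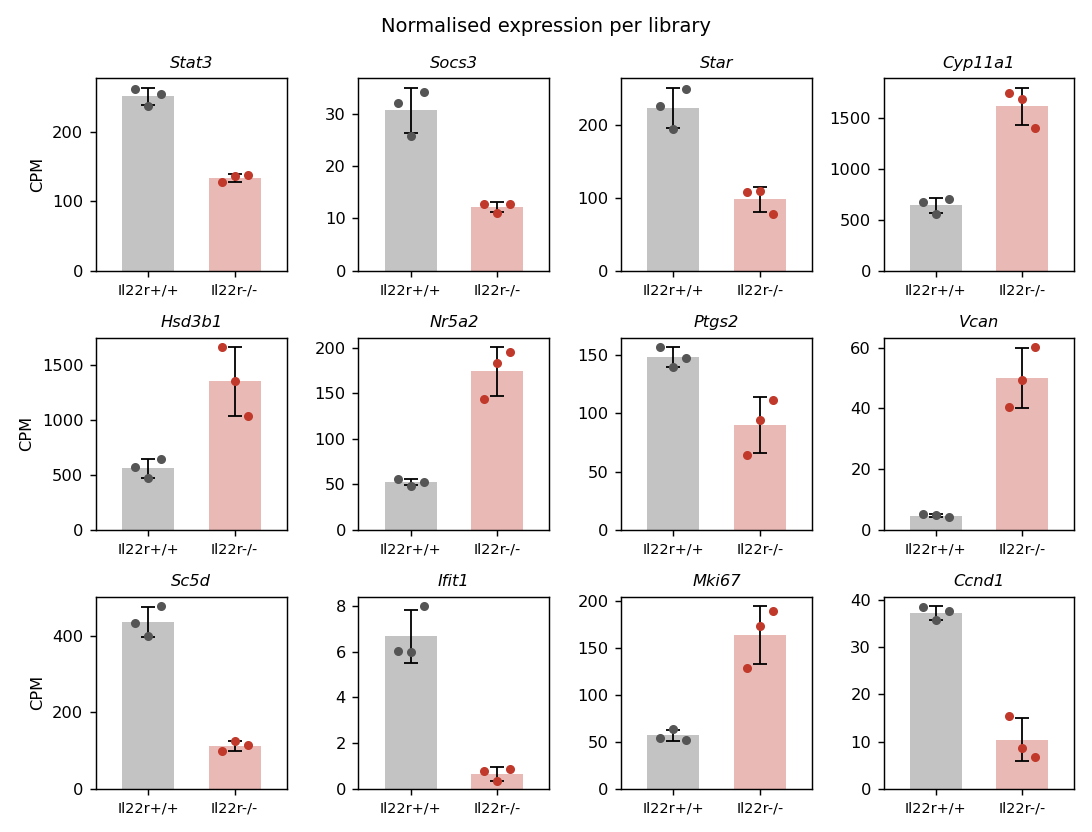
Each panel gives the TMM-normalised CPM of 1 gene, with bars from 0 for the group mean, whiskers for ± SD and points for the 3 libraries of Il22r+/+ (grey) and Il22r-/- (red). Stat3, Socs3, Star, Ptgs2, Sc5d, Ifit1 and Ccnd1 are lower in Il22r-/- and Cyp11a1, Hsd3b1, Nr5a2, Vcan and Mki67 higher, with no overlap between the genotypes, as for Stat3 at 251 ± 12.5 against 134 ± 5.95 CPM.

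Cell cycle genes were higher in Il22r-/-. Of 28 tested members 24 rose, among them the proliferation marker Mki67 (56.9 ± 6.11 to 164 ± 31.3 CPM), the replication helicase subunit Mcm6 (35.5 ± 1.70 to 103 ± 12.7 CPM) and the spindle checkpoint kinase Bub1 (11.1 ± 1.73 to 30.6 ± 4.41 CPM). The 2 members that fell were the D-type cyclins, which drive entry into the cycle: Ccnd1 from 37.2 ± 1.45 to 10.3 ± 4.56 CPM, and Ccnd2, named after its values were seen, from 785 ± 89.8 to 391 ± 44.7 CPM. Counts adjusted over the list alone were the same, and the median log2 change was 1.06. Camera placed the list above other genes (adjusted p = 3.97e-10; adjusted p = 0.294 with an estimated correlation). LTO1 overlaps 23.4% of the Ccnd1 exon length on the other strand.

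Interferon-stimulated genes were lower. Of 16 tested, 14 fell and the remaining 2 did not pass, with the same counts adjusted over the list alone. Ifi44 fell from 3.63 ± 0.817 to 0.221 ± 0.133 CPM, the antiviral RNA-binding genes Ifit3 and Ifit1 fell 11.2-fold and 10.2-fold, and the ubiquitin-like Isg15 fell 8.77-fold. Without Il22r-/- replicate 2 the log2 change of Ifi44 was -4.58 instead of -3.97. The median log2 change was -1.97, and camera called the list lower (adjusted p = 2.53e-08; adjusted p = 0.154 with an estimated correlation). The Ifit genes form a family of similar sequences, and reads shared among its members were not resolved here.

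Cholesterol synthesis and uptake genes fell together, 16 of 20 tested and 19 adjusted over the list alone. Sc5d, a late enzyme of the pathway, fell from 438 ± 39.3 to 112 ± 12.9 CPM, and Fdft1, the squalene synthase, fell 2.12-fold. The list's median log2 change was -0.67, and camera called it lower (adjusted p = 2.53e-08; adjusted p = 0.294 with an estimated correlation). Ctsb overlaps 18.3% of the Fdft1 exon length on the other strand.

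Extracellular matrix genes were mostly lower, 15 of 18 tested, with 2 higher and the same counts adjusted over the list alone. Timp3, an inhibitor of metalloproteinases, fell from 1412 ± 122 to 135 ± 3.04 CPM, the proteoglycan Bgn from 1306 ± 71.7 to 202 ± 61.7 CPM, and the collagen cross-linking enzyme Loxl2 from 708 ± 34.1 to 246 ± 19.8 CPM. Col1a2, also a stromal marker, and the metalloproteinase Mmp11, named after its values were seen, were the members that rose. The median log2 change was -0.84, and camera called the list lower (adjusted p = 8.49e-06; adjusted p = 0.294 with an estimated correlation). Syn3 overlaps 21.3% of the Timp3 exon length on the other strand.

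The remaining pathway lists were not called by camera. Of those in this paragraph, fry called apoptosis and antioxidant genes lower (adjusted p = 0.00127 and 0.0013) and not the others. In apoptosis 6 of 19 members rose and 8 fell, the same adjusted over the list alone (adjusted p = 0.508). The survival gene Bcl2l1 fell from 218 ± 6.35 to 82.7 ± 3.60 CPM, and the pro-apoptotic Pmaip1 and the death receptor Tnfrsf10b fell 3.2-fold and 2.18-fold. Antioxidant genes fell in 6 of 14 cases and rose in 2, the same adjusted over the list alone, led by the quinone reductase Nqo1 (26.9 ± 6.24 to 3.99 ± 0.15 CPM) and the haem oxygenase Hmox1 (212 ± 7.61 to 89.8 ± 12.4 CPM), with the cystine transporter Slc7a11 2.01-fold higher (camera adjusted p = 0.108). Glycolysis and hypoxia genes split 7 higher and 7 lower of 18 (8 and 7 adjusted over the list alone), with Egln3 4.34-fold and Car9 2.14-fold lower and Ndrg1 1.93-fold higher (adjusted p = 0.942, median 0.04 and test direction above 0, mean -0.08). Unfolded protein response genes split 5 and 5 of 14, also adjusted over the list alone, with Atf3 2.32-fold and Pdia4 1.59-fold higher and Herpud1 1.53-fold lower (adjusted p = 0.942, test direction below 0, median 0.01 and mean 0.03). Of 11 inflammation genes Nos2 rose and 3 fell, the same adjusted over the list alone, including the adhesion molecule Icam1 (7.55 ± 0.835 to 1.97 ± 0.574 CPM), with an adjusted p of 0.942, a median of 0.27, a mean of 0.13 and a test direction below 0.

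**Figure D3:**
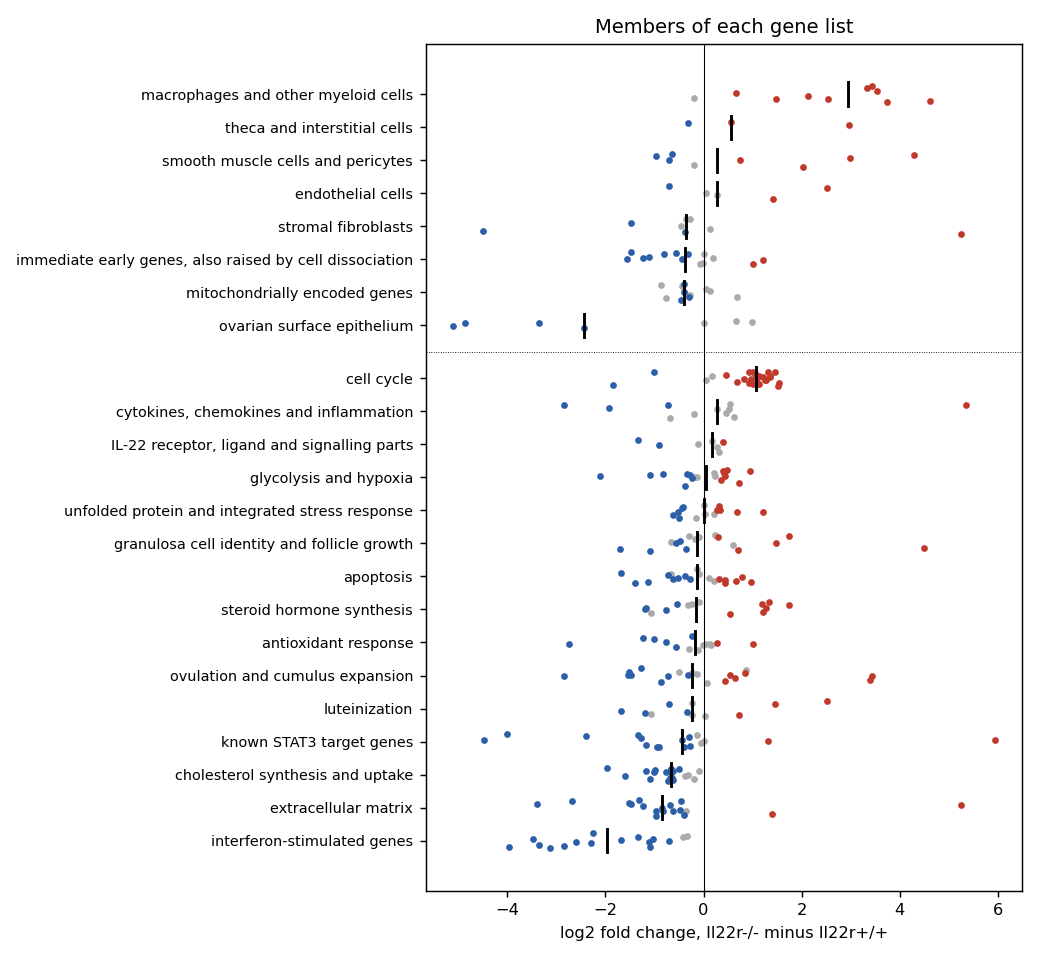
Points are the tested members of each gene list with at least 3 of them, by log2 fold change, Il22r-/- minus Il22r+/+, with black ticks for list medians, and the dotted line parts the pathway lists from the quality and cell type marker lists. Red and blue mark members called higher and lower by edgeR and grey those not called, with medians from -2.44 for ovarian surface epithelium and -1.97 for interferon-stimulated genes to 1.06 for cell cycle and 2.94 for macrophages.

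Markers of cells other than granulosa cells also differed between the genotypes. Of 10 tested macrophage markers 9 rose, the same adjusted over the list alone, with the lysozyme gene Lyz2 at 2.74 ± 0.474 and 29.5 ± 14.8 CPM and the complement gene C1qa at 0.237 ± 0.104 and 3.24 ± 1.92 CPM. Without Il22r-/- replicate 2, C1qa had a log2 change of 3.15 instead of 3.75 and C1qb 2.90 instead of 3.53, and Tyrobp, with 4 reads in all of Il22r+/+, had 5.83 instead of 4.61 without Il22r+/+ replicate 3. Camera called the macrophage list higher (adjusted p = 0.00524; adjusted p = 0.516 with an estimated correlation). Of 7 tested ovarian surface epithelium markers 4 fell, also adjusted over the list alone: Upk1b from 95.6 ± 9.06 to 2.74 ± 1.35 CPM, Msln from 80.3 ± 8.53 to 2.71 ± 1.21 CPM, Upk3b from 46.6 ± 3.34 to 4.50 ± 1.97 CPM and the retinoic acid enzyme Aldh1a2 from 22.2 ± 4.41 to 4.01 ± 2.37 CPM, whose log2 change of -2.44 was -3.04 without Il22r-/- replicate 1. Camera called this list lower (adjusted p = 0.0327; adjusted p = 0.516 with an estimated correlation), and without Il22r-/- replicate 3 its camera adjusted p was 0.0545, in a range from 0.00145 over the alternatives.

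Other marker lists went both ways and were not called by camera. Fry, which tests whether members move on balance in 1 direction, called the stromal list lower (adjusted p = 0.00989). It did not call the smooth muscle and pericyte or the endothelial list (fry adjusted p = 0.171 and 0.148). Of 8 stromal markers (camera adjusted p = 0.18) Col1a2 rose and 3 fell, the same adjusted over the list alone, with the proteoglycan Dcn going from 243 ± 64.2 to 10.6 ± 2.59 CPM and Col3a1 from 300.2 ± 40.2 to 107 ± 18.3 CPM. The third that fell, Ogn (log2 change -0.38, edgeR adjusted p = 0.0374), kept its call with 1 library left out only without Il22r-/- replicate 3. Without Il22r+/+ replicates 1 to 3 and Il22r-/- replicates 1 and 2 the edgeR adjusted p of Ogn was 0.0718, 0.11, 0.101, 0.0782 and 0.105, in a range up to 0.116 over the alternatives. Smooth muscle and pericyte markers split 4 and 3 of 8, the same adjusted over the list alone, with the contractile genes Myh11 and Des 19.5-fold and 4.05-fold higher and Tagln 1.95-fold lower (adjusted p = 0.577). Des lost its call in limma on unfiltered FPKM values (adjusted p = 0.0519, in a range from 5.14e-05 over the alternatives). Gm48529 overlaps 62.4% of the Tagln exon length on the other strand. Among 5 endothelial markers Kdr and Pecam1 were higher (2.52 ± 0.69 and 1.42 ± 0.43) and Tek lower (-0.70 ± 0.25), the same adjusted over the list alone (camera adjusted p = 0.577). All 3 lost the call under some alternatives, where edgeR, limma or DESeq2 adjusted p of Kdr, Pecam1 and Tek reached 0.0866, 0.161 and 0.137. By edgeR, Kdr was not called without Il22r-/- replicate 2 (adjusted p = 0.0575), and its log2 change was 3.12 without Il22r+/+ replicate 3. Pecam1 was not called by edgeR without Il22r+/+ replicate 1, Il22r+/+ replicate 2 or Il22r-/- replicate 2 (adjusted p = 0.0867, 0.0791 and 0.105), nor Tek without Il22r+/+ replicates 2 or 3 or Il22r-/- replicates 2 or 3 (0.0941, 0.137, 0.107 and 0.0541).

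Theca markers were 2 higher, Hpgd 7.84-fold and Ptch1 1.48-fold, and 1 lower, Aldh1a1 1.25-fold, of 3 tested and adjusted over the list alone (camera adjusted p = 0.18). Fry called the theca list higher (adjusted p = 0.00225), a call that rests on these 3 of the list's 7 members. Cyp17a1, also on the list, had 0, 3 and 1 reads in Il22r+/+ and 1, 1 and 0 in Il22r-/-, too few for a test. Aldh1a1 was not called by edgeR with any 1 Il22r+/+ replicate left out (adjusted p = 0.0608, 0.0626 and 0.0667 without replicates 1 to 3), in a range up to 0.0825 over the alternatives. The adipocyte marker Fabp4 was the 1 tested of its list and rose (0.196 ± 0.243 to 1.59 ± 0.447 CPM, called also adjusted over the list alone), with a log2 change of 2.97 that was 4.58 without Il22r+/+ replicate 1. Neither tested oocyte marker passed, over all genes or adjusted over the list alone, with Ddx4 at 0.828 ± 0.309 and 0.794 ± 0.813 CPM and Gdf9 at 0.492 ± 0.203 and 0.701 ± 0.438 CPM. The oviduct marker Ovgp1, at 2.42 ± 0.268 and 2.04 ± 0.202 CPM, did not pass either way, and Gm42890 shares 28.7% of its exon length. Neutrophil, lymphocyte and red cell markers had too few reads for a test, as for Csf3r with none in Il22r+/+ and 4, 14 and 2 in Il22r-/-, Cd79a with 3, 1 and 3 against 7, 10 and 2, and Alas2 with 8, 9 and 2 against 3, 10 and 5.

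Handling and RNA quality markers were also compared. Of 14 immediate early genes 2 rose and 8 fell (3 and 8 adjusted over the list alone), with the shear-responsive factor Klf2 falling 2.34-fold and the heat shock genes Hspa1b and Hspa1a 2.94-fold and 2.81-fold, the latter pair being near-identical copies whose reads cannot be assigned with certainty, and Gm20481 overlaps 19.01% of the Hspa1a exon length. Camera gave an adjusted p of 0.0606, which was 0.0256 without Il22r-/- replicate 3, 0.0394 without Il22r+/+ replicate 2 and 0.0497 without Il22r+/+ replicate 1, in a range up to 0.516 over the alternatives. Fry called the immediate early list lower (adjusted p = 0.0061). Mitochondrially encoded genes took 2.64% to 2.82% of reads in Il22r+/+ and 2.14%, 2.08% and 2.72% in Il22r-/- replicates 1 to 3. Of 12 tested, 4 fell (3 adjusted over the list alone), mt-Nd4, mt-Nd6, mt-Co1 and mt-Cytb with log2 changes between -0.46 and -0.30. With scaling by library size alone mt-Nd6, mt-Co1 and mt-Cytb lost the call (edgeR adjusted p = 0.0604, 0.0682 and 0.148), and over all alternatives their adjusted p reached 0.0955, 0.0998 and 0.172. In edgeR with 1 library left out, mt-Nd6 and mt-Co1 stayed called only without Il22r-/- replicate 3, and mt-Cytb only without Il22r-/- replicate 1 or 3. The adjusted p without Il22r+/+ replicates 1 to 3 and Il22r-/- replicates 1 and 2 was 0.0529, 0.0955, 0.0813, 0.0568 and 0.0786 for mt-Nd6 and 0.0801, 0.0855, 0.0929, 0.0554 and 0.0998 for mt-Co1. For mt-Cytb it was 0.0849, 0.172 and 0.0847 without Il22r+/+ replicates 1 to 3 and 0.151 without Il22r-/- replicate 2. Camera gave the list an adjusted p of 0.18, and 0.0256 without Il22r-/- replicate 3, the lowest of a range up to 0.688.

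A gathering of called genes around the targeted gene was not detected at the planned window, but the smallest window gave a p under the threshold. Within 10 Mb of Il22ra1, 123 of 250 tested genes were called (49.2%), against 45.67% of the remaining genes (odds ratio 1.15, 95% interval 0.89 to 1.49, two-sided Fisher's exact p = 0.277). Within 5 Mb 77 of 139 were called (55.4%, odds ratio 1.48, interval 1.04 to 2.105, Fisher's exact p = 0.0258), and the exact p over the window sizes ran up to 0.491. Fisher's test treats neighbouring genes as independent, which they are not.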

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

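The GC and length correction and the fit without mitochondrially encoded genes were alternatives chosen after seeing the data. Between 5373 and 8243 genes were called over the alternatives, against 6963, none of the shared calls turned direction, and 72.64% to 99.86% of the calls were shared in the same direction. Leaving out 1 library gave 5411 to 8243 calls, 2753 to 4126 higher and 2658 to 4117 lower, with 2036 to 2480 changed at least 2-fold. Against 2181 genes called and changed at least 2-fold, limma on log2(FPKM + 1) gave 954 of its own with a filter and 920 without, and log2(FPKM + 0.1) gave 1649. Adding 1 to small values shrinks their fold changes, but these fits also differ from the main one in test, measure and filter. A replicate block, paired by replicate number, gave 6405 calls, 6291 of them shared, and ended the call of Aldh1a1, mt-Cytb and Tek (adjusted p = 0.0511, 0.0944 and 0.0751 in edgeR), yet deviations of same-numbered libraries correlated at 0.026, -0.0406 and -0.0278, so the labels' numbers show no pairing. Of 15 pathway lists, camera called 5, also with the block and without any 1 library, fry called 8, and 0 were called by camera with an estimated correlation, where STAT3 targets and interferon-stimulated genes had an unadjusted p of 0.0196 and 0.0205. The odds ratio near Il22ra1 was 1.479 at 5 Mb against 1.152 at 10 Mb, and 1.099 to 1.272 with 1 library left out, and the cause was not tested. Of 110 named genes, 96 kept direction and call in every alternative run for them and 0 reversed, while 12 of 105 called ones lost the call in at least 1 alternative and 2 of 5 others gained it. Depth limits genes such as Il22ra1, where 3 counts equal 0.158 to 0.197 CPM.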

Other observations

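The tests on flanking DNA and on fewer surface epithelial cells, and the gene groups in the next paragraphs, were chosen after the result was seen. Genes that the tumour suppressor p53 is known to induce were lower in Il22r-/-. All 8 members of a list picked after their values were seen fell, among them the cell cycle inhibitor Cdkn1a by 1.68 on the log2 scale, and Trp53 itself rose by 0.31. On a second list of 19 p53 targets whose values had not been looked at, 12 fell, among them Phlda3 by 1.68 and the membrane protein gene Perp, which fell by 2.04, and 1 rose, with a median log2 change of -0.54 and a camera p of 5.1e-05 (p = 0.0208 with an estimated correlation), so lower p53 output is a candidate explanation that no protein measurement here tests.

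Csf1, the macrophage growth factor, fell from 272 ± 16.5 to 24.5 ± 2.18 CPM (edgeR quasi-likelihood adjusted p = 8.09e-09) in the same libraries in which macrophage markers rose. Chains of the same collagen moved apart: Col6a3 rose while Col6a1 and Col6a2 fell (log2 changes 4.32, -2.57 and -4.67), and Col1a2 rose while Col1a1 did not pass (-0.35). The interferon-inducible GTPase Irgm1 fell from 82.4 to 6.38 CPM, and 9930111J21Rik2 had 355 reads in Il22r+/+ and 1 in Il22r-/- (ratio 345, exact interval 61.5 to 13700). Bpifb5 had 0 reads in Il22r+/+ and 359 in Il22r-/-, at least 123-fold higher against a floor of 3 counts over the group. A2m had 4 and 409 reads (ratio 105, interval 40.8 to 388).

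The genotypes differed in 6963 called genes. A GC and length trend as the whole cause is argued against by a correction that kept 89.79% of the calls in the same direction. An effect of DNA flanking the targeted gene on its neighbours alone is argued against by calls in 45.67% of the tested genes beyond 10 Mb of Il22ra1, while flanking DNA that acts on distant genes was not tested. Only 1 of the 10 splits of the 6 libraries into 3 and 3, the genotype split, gave as many calls. The highest of the others gave 0 by edgeR (48 to 477 genes at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. The other splits also mix the genotypes in both groups, so the genotype difference widens their spread. They therefore cannot show how many calls would arise without a genotype difference. Genotype and any difference in animals, culture or processing day cannot be told apart, since the labels give no batch. Markers of cells other than granulosa cells also differed, and the share of the calls that a different mix of cells could give was not tested.

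Of the surface epithelium markers, Upk1b, Msln, Upk3b and Aldh1a2 fell, with a mean log2 change of -3.941 (-5.109 to -2.443) that was -3.949 (-5.209 to -2.496) after the GC and length correction, all 4 still called, which argues against such a trend. Averaged within each library, the 4 differed by -4.07 ± 0.38 (SE between libraries), and all 7 tested members were highest in replicate 1 among the Il22r-/- libraries. The 4 were selected by their calls in these same libraries, which enlarges their mean, and all 7 tested members had a mean log2 change of -2.015. In all, 57.14% of the 7 tested members fell, and the others, Krt7, Krt19 and Muc16, had only 1.44, 1.83 and 1.00 CPM in Il22r+/+ beside 95.6 CPM of Upk1b and did not pass (log2 changes 0.98, 0.67 and 0.01). All 5 members of a mesothelial list picked after their values were seen fell, from Bnc1, Gpm6a and Lrrn4 at 64.9-fold, 48.5-fold and 13.7-fold to Krt8 at 1.23-fold. Of these members 2, 2 and 1 were highest in Il22r-/- replicates 1 to 3. Because of that picking, the list's camera p (6.54e-06, or 0.01 with an estimated correlation) gives no support. Genes picked that way cannot decide it, so fewer surface epithelial cells and a change of these genes within granulosa cells cannot be told apart.

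Macrophage markers rose in 9 of 10 tested cases. In a second macrophage list, 60% of 5 tested members rose (Laptm5, Cybb and Mpeg1), while Cd52 and Fcgr3 did not pass (-1.09 and -0.04), and camera did not call the list (p = 0.161, or 0.468 with an estimated correlation). The list's 8 members below the test's filter all had more summed reads in Il22r-/-, but unevenly: Rac2 had 0, 0 and 0 against 10, 15 and 8, Cx3cr1 0, 4 and 0 against 15, 27 and 6, and Cd53 8, 6 and 5 against 19, 25 and 4, while Spi1 and Ms4a7 had 0 in Il22r-/- replicate 3. All 9 called markers had the order of replicates 2, 1 and 3 from highest to lowest in Il22r-/-, as had 2 of the 3 called members of the second list and 258 of 1222 genes at least 2-fold higher (21.1%). Macrophages carried into the cultures may contribute, but the share fell short of the 2 in 3 set for them with only 5 members tested, and Cd52 and Fcgr3, at about 1 and 2 CPM in Il22r+/+, exclude nothing, so the source stays open.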
